A study of Rattus norvegicus with 24 samples.

How the data were processed

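Total RNA from cartilage zones of the proximal tibia of 1-week-old rats was measured on Affymetrix arrays, with 50 to 100 ng of RNA amplified in a pair of cycles and labelled with biotin, per the labels' protocols. Stained frozen sections were separated by hand into zones, per the labels' protocols. The deposited values are intensity values, 1 MAS5 signal per probe set on a linear scale, per the submitters' processing notes, and the MAS5 version is not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets lay between 500.1 and 500.2 in every array, as it does after scaling to one trimmed mean. No detection p-values were used here. The files held 31099 probe sets in 24 arrays.

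What was computed from these values starts at log2(signal + 16), with no further normalization. The 57 control probe sets were left out, and a probe set was tested when it lay above its array's median in at least 4 arrays, which left 19213 (61.8%). Gene names came from the platform annotation, updated by gene identifier to the current rat gene table of assembly GRCr8. Over the tested probe sets, 13956 had 1 symbol, 323 several and 4934 none, and only those with 1 symbol were named. A gene was represented by its tested probe set of highest mean log2 signal over the 24 arrays, which gave 10558 genes. Some genes of the lists were not analysed here.

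The labels tie each array to a numbered animal, so zones of 1 animal are not independent, and the animal entered the fit as a fixed block. Deviations from the zone mean correlated at a median r across probe sets of 0.176 between same-numbered arrays of different zones (46 pairs, from -0.142 to 0.36) and of -0.046 between arrays of different numbers (184 pairs), and 21 of 24 arrays matched their own number best. The transition arrays of animals 4 and 5 and the hypertrophic array of animal 4 did not. No arrays were duplicates: at most 50 values were identical between any 2 arrays of a zone, and the smallest root mean square difference was 0.617 on the log2 scale.

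Zones were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on all 24 arrays, which share 1 estimate of the spread per probe set, with 15 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and a call needed an adjusted p below 0.05 and a fold of at least 2. The 22 gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over all 110 tests. The 5 comparisons, their tests, the gene lists, the rule for named genes and the settings named as fixed in advance were chosen before the data were examined, and the added settings and most tests of explanations and of gene families later. That rule takes every tested member of the hedgehog list in each comparison, the 8 largest rises and 8 largest falls among called genes with 1 symbol that moved the same way in every animal with both zones, and up to 4 members of each other list with the smallest adjusted p. The text names genes from these. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

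The test was tried on simulated data with the real means, spreads and animal effects over 19213 probe sets. In each simulated comparison 100 probe sets were changed 3-fold and 100 were changed 6-fold. For the hypertrophic against the proliferative zone it recovered 85 of the 3-fold and 98 of the 6-fold changes with 3 false calls, and for the resting zone against epiphyseal cartilage 76 and 94 with 5 false calls. In each comparison camera called the 1 shifted list and 0 of 19 unshifted lists. The simulated lists were drawn at random and their noise was independent between genes. Camera was therefore not tried on lists whose genes move together.

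The settings fixed in advance were a pseudocount of 1 or 64, quantile normalization, scaling to one median, no filter, a filter at the 75th percentile, no replicate block, a random block, only the zones compared, no trend, array weights and leaving out each animal in turn. For the lists, an estimated correlation and the mean of a gene's probe sets were added. Settings chosen after the data were seen left out the transition array of animal 5, the hypertrophic array of animal 4 or the epiphyseal arrays of animals 1 and 2, or took the mean log2 signals of the erythroid, osteoclast and muscle markers as covariates. Those scores are nearly collinear with the hypertrophic zone. Outlying arrays were looked for in 125 groups: the zone levels of the hedgehog list, marker list means and 4 quality measures, and not in every named gene. The ratio of 3' to 5' signal, a measure of RNA quality, had a log2 mean for Gapdh between 2.573 in the transition zone and 2.956 in the hypertrophic zone, with SDs of 0.328 and 0.536. For actin the log2 mean was 4.03 ± 0.674 (SD) in epiphyseal cartilage, 4.027 ± 0.254 in the resting, 4.47 ± 0.307 in the proliferative, 4.46 ± 0.185 in the transition and 4.308 ± 0.303 in the hypertrophic zone.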

Results

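Gene expression was measured in cartilage of the proximal tibia of 1-week-old rats, which was cut into 60 µm frozen sections and separated by hand under a microscope into zones. The growth plate is the cartilage in which long bones lengthen: resting cells give rise to columns of proliferative cells. These stop dividing, enlarge as hypertrophic cells and mineralize their matrix before bone replaces them. The 24 arrays covered epiphyseal cartilage (n = 4) and the resting, proliferative, transition (proliferative to hypertrophic) and hypertrophic zones (n = 5 each) of 5 numbered animals. The labels of the resting, proliferative and hypertrophic arrays name male rats, and those of the other arrays give no sex. The array median signal ranged from 135.3 to 244.6. The number of arrays limits the precision of every value. Of 19213 probe sets tested, 10674 (55.6%) differed across the 5 zones in limma's moderated F test at an adjusted p below 0.05. The first principal component held 28.4% of the variance and the second 16.7%. Zones were compared with limma with the animal as a block, and a probe set was called at an adjusted p below 0.05 and a fold of at least 2. Fold changes are on the log2(signal + 16) scale, which understates the change of dim probe sets, and errors of fold changes are standard errors of the fit.

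**Figure D1:**
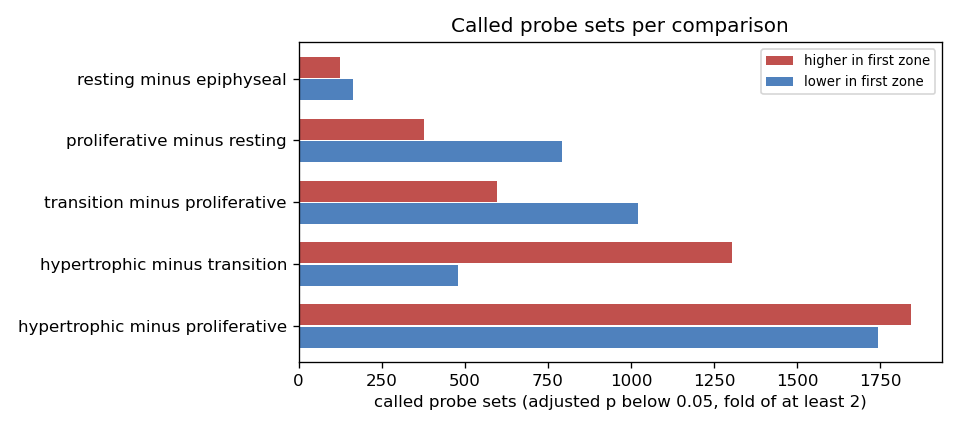
Horizontal bars starting at 0 give the number of called probe sets (x axis) in each of the 5 comparisons (y axis), with those higher in the first-named zone in red and those lower in blue. The counts run from 125 higher and 165 lower between resting and epiphyseal cartilage to 1843 higher and 1742 lower between the hypertrophic and proliferative zones.

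The title of the series names Indian hedgehog signalling, so the members of the hedgehog and parathyroid hormone-related protein system were followed through all zones. Ihh, the hedgehog ligand of the growth plate, had a mean signal of 160.6 ± 29.15 (SD, n = 5) in the resting zone, 635.1 ± 329.9 (n = 5) in the proliferative zone, 8285 ± 2254 (n = 5) in the transition zone and 10410 ± 2496 (n = 5) in the hypertrophic zone. Its mean in epiphyseal cartilage was 295.6 ± 225 (n = 4). Gli1, a transcription factor gene induced by hedgehog signalling, peaked in the proliferative zone at 1901 ± 669 (SD, n = 5), against 912.2 ± 339.9 in the resting zone, 371.2 ± 136.8 in the transition zone, 45.5 ± 26.11 in the hypertrophic zone and 121.6 ± 81.02 (n = 4) in epiphyseal cartilage. Hhip, which encodes a hedgehog-binding inhibitor, and Boc, a hedgehog co-receptor gene, had their highest means in the resting zone, at 496.5 ± 108.4 and 9668 ± 904.6. In epiphyseal cartilage the mean was 68.75 ± 30.12 for Hhip and 7905 ± 2063 for Boc (n = 4). Pth1r, the receptor gene of parathyroid hormone-related protein, had its lowest mean in the resting zone, at 5917 ± 1569, and its highest in the hypertrophic zone, at 36460 ± 10280. Of the 20 members of the list, 12 were tested and 9 differed across zones, adjusted over all probe sets (also 9 adjusted over the list alone). They were Ihh, Gli1, Boc, Pth1r, Smo, Gli2, Hhip, Disp1 and Kif7. The same F test passed 55.6% of all tested probe sets. It spans the epiphyseal and transition arrays, whose labels are worded differently from the others, so it cannot part batch from zone. Dhh, Sufu and Stk36 did not pass the test, with adjusted p of 0.636, 0.0939 and 0.526. The other 8 members were not analysed here.

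**Figure D2:**
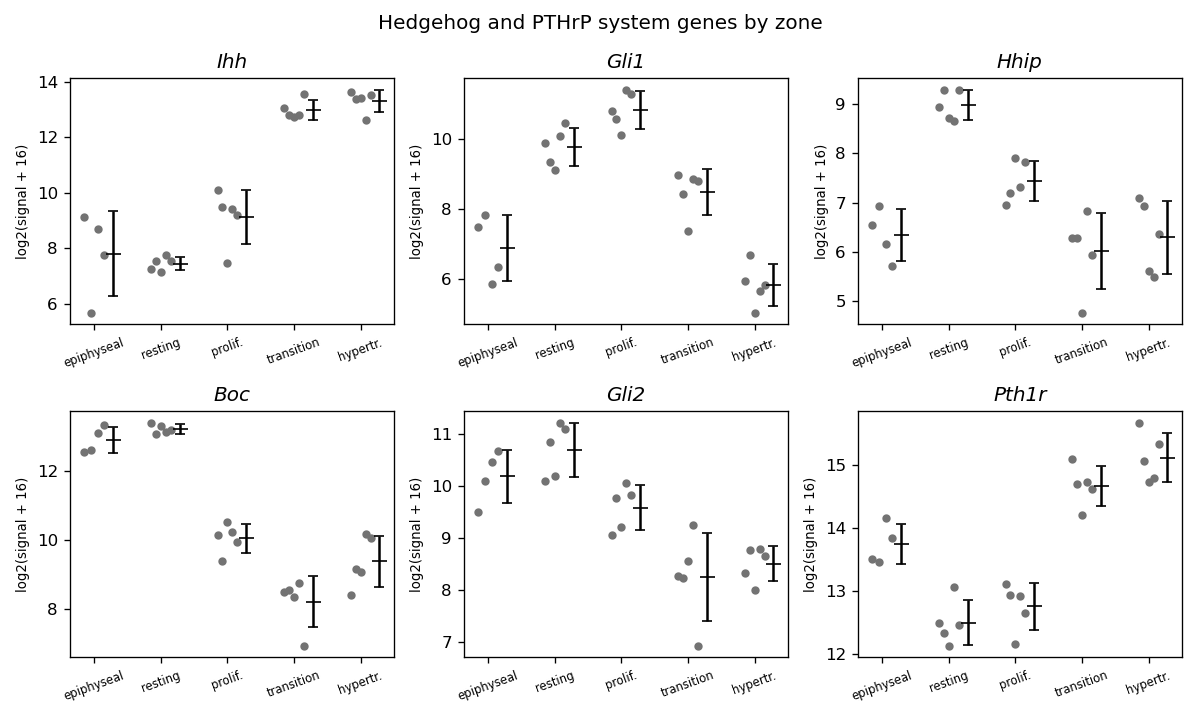
Each panel plots log2(signal + 16) (y axis) of 1 gene in the 5 zones (x axis), with a point per array and the mean with its SD beside the points. Ihh has its highest mean in the hypertrophic zone (13.31) and Gli1 in the proliferative zone (10.83), while Hhip, Boc and Gli2 have theirs in the resting zone.

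Epiphyseal cartilage was compared with the adjoining resting zone. Gli1 and Hhip were higher in the resting zone, by log2 fold changes of 3.09 ± 0.33 (adjusted p = 2.82e-06) and 2.75 ± 0.41 (adjusted p = 0.000235), in 4 of 4 animals each. Nptx1 (3.74 ± 0.48), Itih3 (3.01 ± 0.30), Adgrb1 (2.58 ± 0.39), Cxcr4, a chemokine receptor gene (2.46 ± 0.30), Bmper, a regulator of bone morphogenetic proteins (2.45 ± 0.36), and Sfrp5, a secreted Wnt inhibitor (2.39 ± 0.36), also rose. Col10a1, the collagen of hypertrophic cartilage, fell by 3.38 ± 0.50, Alpl, an alkaline phosphatase gene, by 3.13 ± 0.36, and Phospho1, a phosphatase gene of mineralization, by 1.80 ± 0.24 on the log2 scale. Of 16 hypertrophy genes, 2 fell and 1 rose (3 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.101). S100a6 fell by 2.55 ± 0.22, Wnt4 by 2.38 ± 0.28, Gpx2 by 2.45 ± 0.45, Fam151a by 2.74 ± 0.29 and Pth1r by 1.13 ± 0.18. Ihh itself was not called, at -0.24 ± 0.43 (adjusted p = 0.876).

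Among 25 tested genes of bone morphogenetic protein signalling, 2 rose and 3 fell between epiphyseal and resting cartilage (2 and 5 adjusted over the list alone), with Bmp2 at -1.75 ± 0.20, Bmp6 at -1.35 ± 0.27 and Id2 at -1.16 ± 0.20. The Bmp6 call did not hold without replicate 2 (adjusted p = 0.0827). The list passed camera downward (adjusted p = 0.00288), and not with an estimated correlation (adjusted p = 0.122 with an estimated correlation). Of 13 mineralization genes, 3 of which are also on the hypertrophy list, 2 fell and none rose (3 fell adjusted over the list alone). The mineralization list passed camera (adjusted p = 0.0108), and not with an estimated correlation (adjusted p = 0.183). Without the epiphyseal arrays of animals 1 and 2 that list did not pass camera (adjusted p = 0.211). Of 12 immediate-early and stress genes, which respond to handling as well as to signals, 2 fell (3 adjusted over the list alone), Hspb1 at -1.85 ± 0.33, with a camera adjusted p of 0.00638 (adjusted p = 0.39 with an estimated correlation) and of 0.76 without those arrays. Skeletal muscle markers had a mean log2 fold change of 1.224 (camera adjusted p = 2e-04; adjusted p = 0.395 with an estimated correlation), with 1 of 12 called (5 adjusted over the list alone). The difference of their mean log2 signal, resting minus epiphyseal, was -0.34, 0.77, 0.35 and 2.49 in animals 1, 2, 4 and 5. The list of osteoclast and macrophage markers was lower in the resting zone, at a mean log2 fold change of -1.342, with 0 of 13 members called (3 adjusted over the list alone) and a camera adjusted p of 1.93e-05 (adjusted p = 0.395 with an estimated correlation). The difference of its mean log2 signal was -1.86, -3.14, -0.6 and 0 in animals 1, 2, 4 and 5, and without the epiphyseal arrays of animals 1 and 2 the list did not pass (mean 0.297, adjusted p = 0.461). Endothelial markers had a mean of -0.834, with 0 of 8 called (0 adjusted over the list alone), a camera adjusted p of 0.0253 (adjusted p = 0.551 with an estimated correlation) and differences of -1.36, -2.31, -0.39 and 0.88 in these animals. Without the same arrays that list did not pass either (mean 0.639, adjusted p = 0.461). In all, 125 probe sets were higher and 165 lower in the resting zone. Without replicate 2 these counts were 68 and 69. Without the epiphyseal arrays of animals 1 and 2, left out after the data were seen, 114 were higher and 105 lower. Of the 290 calls, only 128 were also made without replicate 2 and 145 without those epiphyseal arrays. The labels of the epiphyseal and transition arrays are worded differently from those of the other zones, so in this comparison batch and group cannot be told apart.

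The resting and proliferative zones, whose labels share their wording, were compared next. Panx3, a channel gene of maturing chondrocytes, rose by a log2 fold change of 4.54 ± 0.28 (adjusted p = 9.41e-11) in 5 of 5 animals, Gdf10 by 3.93 ± 0.36, Cldn10 by 3.26 ± 0.31, Dlx5 by 3.22 ± 0.33, Runx3 by 2.93 ± 0.17, Wnt5b by 2.51 ± 0.17 and Wnt4 by 2.46 ± 0.26. Grem1, a secreted inhibitor of bone morphogenetic proteins, fell, at -5.49 ± 0.39 (adjusted p = 5.19e-10). The Wnt inhibitors Sfrp5 and Frzb fell too, at -3.88 ± 0.33 and -1.69 ± 0.17. Further falls were those of Bmp3 (-4.73 ± 0.42), Abi3bp (-4.35 ± 0.32), Serpine2 (-4.24 ± 0.33), Vegfc (-4.06 ± 0.42) and Efemp1 (-3.63 ± 0.36). In the hedgehog system Ihh rose by 1.68 ± 0.40 (adjusted p = 0.00504) and Gli1 by 1.05 ± 0.31 (adjusted p = 0.0236). Boc (-3.18 ± 0.29), Hhip (-1.54 ± 0.39) and Gli2 (-1.11 ± 0.27) fell. The Gli1 call did not hold with no replicate block (adjusted p = 0.0734) or without replicate 1 (adjusted p = 0.0584) or 3 (adjusted p = 0.0749), and with array weights or without replicate 4 the change was just under 2-fold, at 0.992 (adjusted p = 0.0116) and 0.987 (adjusted p = 0.0481). The Hhip call did not hold without replicate 2 (adjusted p = 0.0707).

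Of 11 tested genes of the epiphysis and joint surface list, 6 fell in the proliferative zone and none rose (also 6 adjusted over the list alone), among them Vit at -3.16 ± 0.30 and Dcn at -3.08 ± 0.31, with a camera adjusted p of 3.49e-06 (adjusted p = 0.0879 with an estimated correlation). The cell cycle list was higher as a group (mean log2 fold change 0.744, camera adjusted p = 6.96e-07; adjusted p = 0.39 with an estimated correlation), although only Cks2 of 26 members was called, at 1.13 ± 0.15 (2 adjusted over the list alone). Among 16 hypertrophy genes 4 rose and 4 fell (4 and 4 adjusted over the list alone), Fgfr1 falling by 1.77 ± 0.21. In the growth hormone and insulin-like growth factor list, 4 of 14 fell and 1 rose (4 and 1 adjusted over the list alone), with Igf1 at -2.57 ± 0.55. Markers of skeletal muscle fell in 7 of 12 members (9 adjusted over the list alone), with Tnni2 at -2.63 ± 0.16 and a camera adjusted p of 1.56e-05 (adjusted p = 0.352 with an estimated correlation). The muscle list varied between resting arrays, at a mean log2 signal of 10.7 ± 1.87 (SD, n = 5), against 8.91 ± 0.63 (n = 5) in the proliferative zone. The log2 ratio of 3' to 5' actin signal, a measure of RNA quality, was 4.47 ± 0.307 (SD, n = 5) in the proliferative and 4.027 ± 0.254 (n = 5) in the resting arrays. It was higher in the proliferative array of 5 of 5 animals, by a mean of 0.444 (exact sign-flip p = 0.0625, two-sided, the smallest that 5 animals allow), in 1 of 10 such tests, none of which passed after adjustment. In all, 378 probe sets were higher and 792 lower, so 32.3% of calls were higher, against 42.6% when arrays were scaled to one median.

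The transition zone was compared with the proliferative zone. Alpl rose by a log2 fold change of 4.51 ± 0.33 (adjusted p = 8.99e-10), Sgsm1 by 4.41 ± 0.30, F13a1, which encodes a transglutaminase subunit, by 4.08 ± 0.31, Col10a1 by 4.08 ± 0.46, Aldh1a3, a retinoic acid synthesis gene, by 3.96 ± 0.37, and Ihh by 3.85 ± 0.40 (adjusted p = 1.63e-07), each in 5 of 5 animals. Pth1r rose by 1.91 ± 0.16, Phospho1 by 2.88 ± 0.23, Bmp6 by 2.62 ± 0.25, Bmp2 by 2.18 ± 0.19 and Hspb1 by 2.80 ± 0.31. Brca2 (-3.51 ± 0.48), Ska1 (-3.23 ± 0.29), Kif23 (-2.95 ± 0.25), Nusap1 (-2.86 ± 0.19) and Mki67, a marker of dividing cells (-2.71 ± 0.24), fell. Gli1 fell by 2.33 ± 0.31 on the log2 scale (adjusted p = 5.6e-06), and Boc (-1.84 ± 0.29), Gli2 (-1.34 ± 0.27) and the Wnt inhibitor Sfrp1 (-2.49 ± 0.18) fell as well. Without replicate 5 the change of Gli2 was under 2-fold, at -0.942 (adjusted p = 0.0013), as it was without the transition array of animal 5 alone, at -0.92 (adjusted p = 0.000521).

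Of 26 tested cell cycle genes, 24 fell and none rose in the transition zone (25 fell adjusted over the list alone), with a camera adjusted p of 3.95e-19 (adjusted p = 0.122 with an estimated correlation). Of 16 hypertrophy genes, 7 rose and none fell (also 7 adjusted over the list alone), with Mef2c at 1.51 ± 0.16 and Foxa2 at 1.56 ± 0.18 and a camera adjusted p of 0.00372 (adjusted p = 0.122 with an estimated correlation). In the mineralization list 4 of 13 rose (also 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.101). In all, 598 probe sets were higher and 1021 lower, so 36.9% of calls were higher, against 53.6% when arrays were scaled to one median. That scaling moved the median over all probe sets from -0.065 to 0.09. The transition arrays share the label wording of the epiphyseal arrays, so over this comparison as a whole batch and group cannot be told apart. Between the hypertrophic and proliferative arrays, which share theirs, Alpl, Col10a1 and Ihh rose as well, and 13 of 26 cell cycle genes fell (13 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation).

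The hypertrophic zone was compared with the transition zone. St6galnac2 rose by a log2 fold change of 4.64 ± 0.41 (adjusted p = 2.48e-08), Cfap100 by 4.55 ± 0.57, Itgb3, an integrin gene of osteoclasts and platelets, by 4.40 ± 0.59, Ero1b by 3.99 ± 0.37, Medag by 3.74 ± 0.34, Igf1 by 3.72 ± 0.55, Fgfr1 by 3.03 ± 0.21, Ibsp, a bone matrix sialoprotein gene, by 3.02 ± 0.39 and Lrp4 by 2.85 ± 0.30. Gdf10 (-3.75 ± 0.36), Car9, a carbonic anhydrase gene induced by low oxygen (-3.15 ± 0.36), Prelp (-3.06 ± 0.27), Kctd4 (-2.85 ± 0.20), Matn2 (-2.78 ± 0.21) and Gli1 (-2.65 ± 0.31) fell. Ihh was not called between these zones, at 0.32 ± 0.40 (adjusted p = 0.614). Of 13 mineralization genes, 7 rose (also 7 adjusted over the list alone), with Mepe at 2.64 ± 0.42 and a camera adjusted p of 0.0121 (adjusted p = 0.183 with an estimated correlation).

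Markers of blood, marrow and bone cells moved with the hypertrophic zone. All 6 tested erythroid genes rose (6 adjusted over the list alone), with Hbb, a haemoglobin gene, at 2.66 ± 0.29 and a mean signal of 16470 ± 5638 (SD, n = 5) against 2892 ± 1579 (n = 5) in the transition zone (camera adjusted p = 9.13e-07; adjusted p = 0.122 with an estimated correlation). All 6 leukocyte genes rose (6 adjusted over the list alone), with S100a9 at 2.55 ± 0.40 (camera adjusted p = 0.000148; adjusted p = 0.122 with an estimated correlation). Of 13 osteoclast and macrophage genes 10 rose (11 adjusted over the list alone), with Acp5 at 3.61 ± 0.81 (camera adjusted p = 3.54e-05, and 0.412 with an estimated correlation). Of 5 osteoblast genes 4 rose (4 adjusted over the list alone), with Col1a1 at 2.64 ± 0.40 (camera adjusted p = 0.00288, and 0.172 with an estimated correlation). Of these 5 genes, 3 are also on the mineralization list and 2 on the perichondrium and fibroblast list. Of 12 muscle genes 7 rose (7 adjusted over the list alone; camera adjusted p = 0.000742; adjusted p = 0.419 with an estimated correlation). Of 14 perichondrium and fibroblast genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00653; adjusted p = 0.447 with an estimated correlation), and the list did not pass without replicate 4 or without the hypertrophic array of animal 4 alone (adjusted p = 0.0768). Of 12 immediate-early and stress genes, 6 rose (6 adjusted over the list alone), with Egr1 at 2.10 ± 0.38 and Dusp1 at 1.53 ± 0.28 (camera adjusted p = 0.00764; adjusted p = 0.39 with an estimated correlation). Cell cycle genes moved the same way, 6 of 26 rising (6 adjusted over the list alone) with Mki67 at 2.02 ± 0.24 (camera adjusted p = 3.54e-05; adjusted p = 0.447 with an estimated correlation). In all, 1303 probe sets were higher and 478 lower, so 73.2% of calls were higher. When arrays were scaled to one median, 880 were higher and 1163 lower (43.1% higher), and the median over all probe sets was -0.241 in place of 0.016. With quantile normalization 60.7% were higher. With scores of 3 marker lists as covariates, a setting chosen after the data were seen, 11 were higher and 5 lower. These scores follow the hypertrophic zone closely, so that the design alone widened the standard errors by a factor of 2.63, and the median standard error was 0.601 in place of 0.242. Over this comparison as a whole batch and group cannot be told apart, but the mean change of the 30 tested erythroid, leukocyte, osteoclast and osteoblast markers was 2.462 ± 0.357 (SE) between the hypertrophic and proliferative arrays, which share their label wording.

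**Figure D3:**
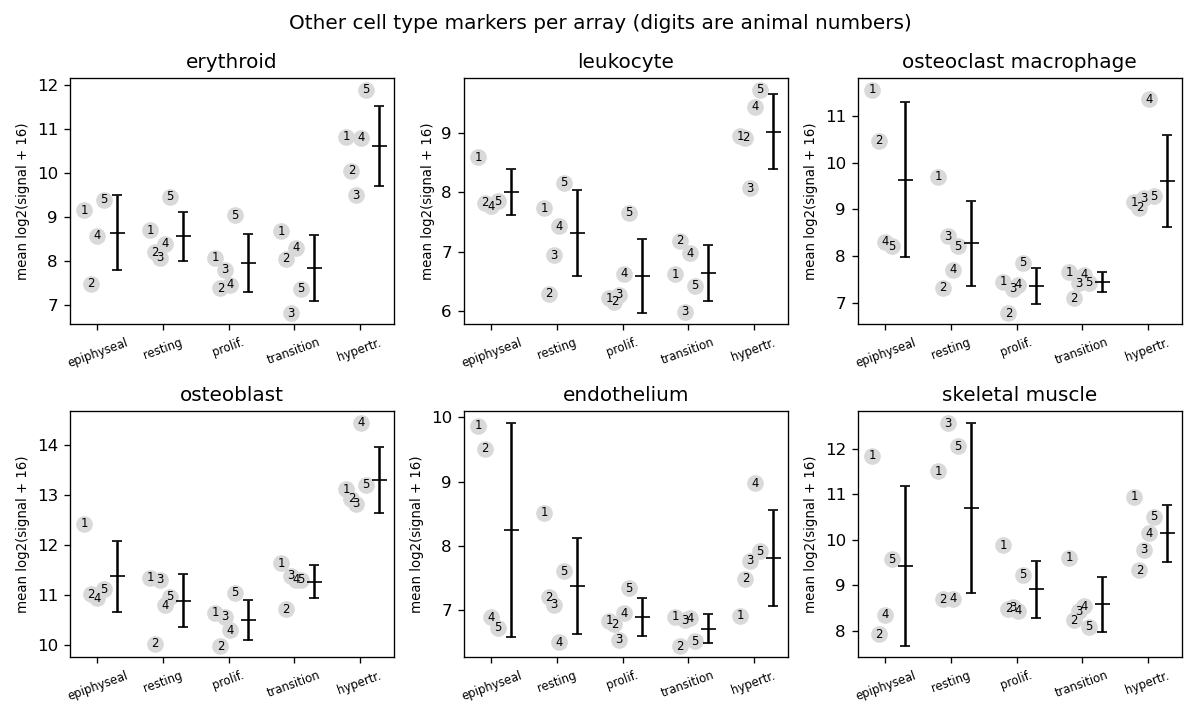
Each panel plots the mean log2(signal + 16) of the tested markers of 1 cell type (y axis) in the 5 zones (x axis), with a point per array carrying its animal number and the zone mean with its SD beside them. The erythroid mean is 10.62 in the hypertrophic zone and 7.85 in the transition zone, and the hypertrophic array of animal 4 lies apart for osteoclast and osteoblast markers.

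The hypertrophic and proliferative zones share their label wording and gave the most calls. F13a1 rose by a log2 fold change of 6.36 ± 0.31 (adjusted p = 8.78e-14), Aldh1a3 by 6.28 ± 0.37, Gpx2 by 5.93 ± 0.42, Alpl by 5.86 ± 0.33, Sgsm1 by 5.83 ± 0.30, Slco2b1 by 5.78 ± 0.46, Irx5 by 5.33 ± 0.41, Ibsp by 5.07 ± 0.39 and Col10a1 by 4.85 ± 0.46. Ihh rose by 4.17 ± 0.40 (adjusted p = 1.17e-08), and Pth1r by 2.36 ± 0.16. Gli1 fell by 4.99 ± 0.31 on the log2 scale (adjusted p = 7.29e-12), and Kif7 (-1.32 ± 0.19) and Smo, the hedgehog signal transducer (-1.31 ± 0.17), fell too. The largest falls included Gdf10 (-6.11 ± 0.36), Car9 (-4.75 ± 0.36), P4ha3 (-4.37 ± 0.28) and Kctd4 (-4.20 ± 0.20). Adgrb1 (-4.15 ± 0.36), Prelp (-3.93 ± 0.27) and Sfrp1 (-3.48 ± 0.18) fell as well.

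Of 16 hypertrophy genes, 11 rose and 2 fell between the proliferative and hypertrophic zones (11 and 2 adjusted over the list alone), with Foxa2 at 3.15 ± 0.18 and a camera adjusted p of 2e-04 (adjusted p = 0.0879 with an estimated correlation). Of 13 mineralization genes, 3 of which are also on the hypertrophy list, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00175; adjusted p = 0.122 with an estimated correlation). Of 26 cell cycle genes, 13 fell and none rose (13 adjusted over the list alone), with Mcm2, a replication gene, at -2.08 ± 0.27 (camera adjusted p = 1.51e-05; adjusted p = 0.419 with an estimated correlation). In the list of hypoxia and glycolysis genes 5 of 21 fell and none rose (5 and 1 adjusted over the list alone), with Bnip3 at -1.36 ± 0.21 (camera adjusted p = 0.0116; adjusted p = 0.642 with an estimated correlation). Without the hypertrophic array of animal 4 that list did not pass (adjusted p = 0.0515). Blood cell markers were higher here too: 6 of 6 erythroid and 6 of 6 leukocyte genes rose (6 and 6 adjusted over the list alone), with camera adjusted p of 0.000116 and 0.00219 (adjusted p = 0.197 and 0.183 with an estimated correlation). Of 5 osteoblast genes, 3 of which are also on the mineralization list, 4 rose (4 adjusted over the list alone), with Col1a2 at 2.71 ± 0.26 (camera adjusted p = 0.000467; adjusted p = 0.122 with an estimated correlation). Of 13 osteoclast and macrophage genes 9 rose (9 adjusted over the list alone; camera adjusted p = 0.000677; adjusted p = 0.522 with an estimated correlation). In the immediate-early and stress list 6 of 12 rose (6 adjusted over the list alone), Hspb1 by 3.34 ± 0.31 (camera adjusted p = 0.00288; adjusted p = 0.352 with an estimated correlation). Of 12 muscle genes 1 rose (7 adjusted over the list alone), at a list mean of 1.234 that was above 0 in 5 of 5 animals, from 0.85 to 1.71 (camera adjusted p = 0.0369; adjusted p = 0.65 with an estimated correlation). That list did not pass with no replicate block (adjusted p = 0.0851), without the hypertrophic array of animal 4 (adjusted p = 0.0634), without replicate 1, with a random block or with the filter at the 75th percentile. In all, 1843 probe sets were higher and 1742 lower (51.4% higher), against 1624 and 2112 (43.5% higher) when arrays were scaled to one median, which moved the median over all probe sets from -0.049 to -0.152. With the marker scores as covariates the counts were 617 and 665.

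**Figure D4:**
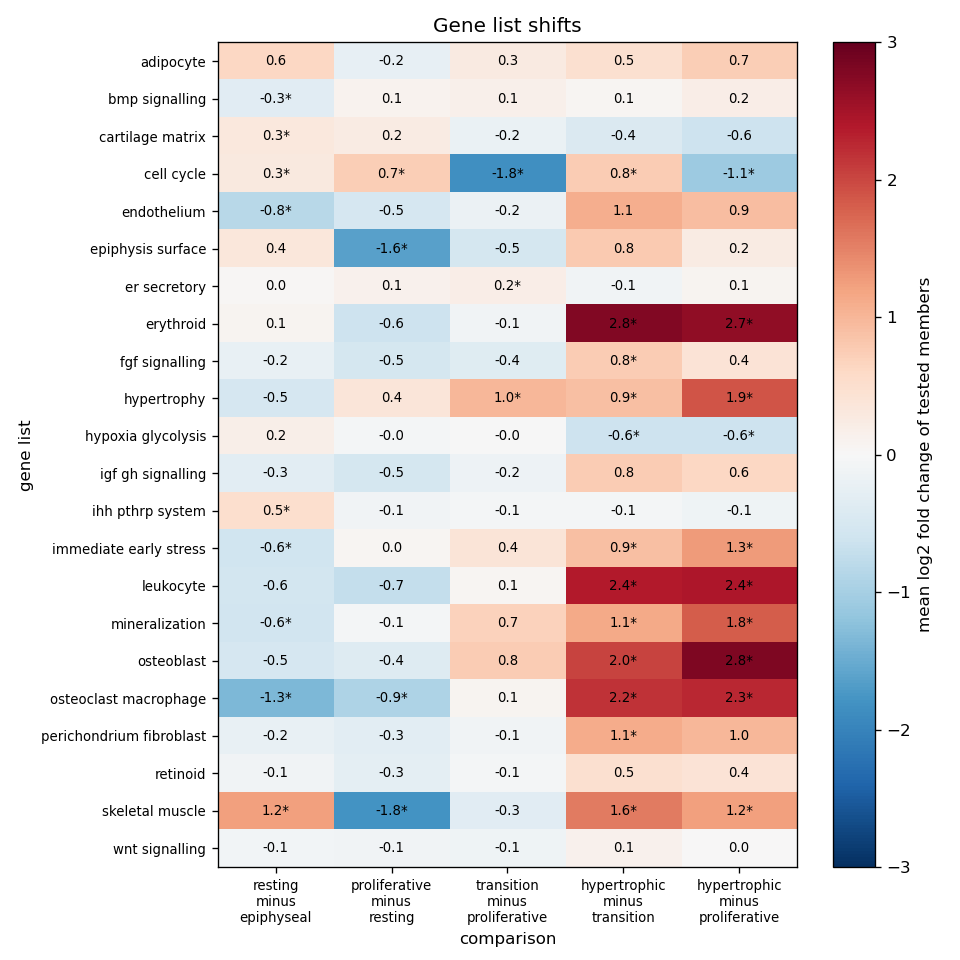
The colour and the printed number in each cell give the mean log2 fold change of a gene list's tested members (y axis, 22 lists) in each comparison (x axis), with an asterisk at a camera adjusted p below 0.05 with a preset correlation of 0.01. The asterisks number 38 of 110, and with an estimated correlation 0 of 110 passed.

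Over all comparisons, 38 of 110 list tests passed camera with the preset correlation, 0 with an estimated correlation and 45 passed fry, which does not compare a list with other genes.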

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

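The tests on the share of rising blood and bone markers, on the cell type lists against each other, on a batch of the transition arrays, on median scaling and quantile normalization, on the epiphyseal arrays of animals 1 and 2 and on the marker scores were chosen only after values bearing on them had been seen. The tests on strongly hypertrophic genes and on the batch slope were not. Of 125 groups of 4 or 5 arrays, 9 held an array far from the others, where chance gives about 1 in 20.

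In the hypertrophic zone the array of animal 4 stood apart in 4 values: Ihh was lower, at a log2 signal of 12.6 against 13.36 to 13.64 in the others, while the means of osteoblast markers (14.45 against 12.82 to 13.21), osteoclast and macrophage markers (11.35 against 9.03 to 9.29) and perichondrium and fibroblast markers (11.42 against 9.39 to 9.71) were higher. In epiphyseal cartilage the array of animal 1 was high for leukocyte markers (8.59 against 7.77 to 7.85) and osteoblast markers (12.42 against 10.93 to 11.11). The median signal of the epiphyseal array of animal 5 was 244.6 against 170.9 to 180.8. Boc was low in the transition array of animal 5, at 6.92 against 8.36 to 8.76, and Sufu in the proliferative array of animal 3, at 6.24 against 7.46 to 7.96.

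Blood, marrow and bone cell markers were higher in the hypertrophic than in the transition arrays. Median scaling in place of the authors' scaling left 96.2% of the 26 called members called. It moved the median over all probe sets from 0.016 to -0.241. The mean change of the 30 tested markers was far larger, at 2.309 ± 0.357 (SE). Such a move could end few of these calls, so their share cannot test the authors' scaling. These values show only that the choice between these scalings does not account for the rise. A batch of the transition arrays is argued against as the whole source. The mean change of the 30 markers was 2.462 ± 0.357 (SE) between the hypertrophic and proliferative arrays, which share their label wording. After adjustment, 4 of 21 pairs of lists moved apart. The mean change of the erythroid list, taken as reference for its highest mean, exceeded that of perichondrium and fibroblasts by 1.668 ± 0.472 (SE over arrays). That of osteoclasts and macrophages exceeded the endothelial one by 1.064 ± 0.189. These differences cannot decide whether a lower share of chondrocytes raised every other cell type alike, since a log2 change also depends on the starting level. In the transition arrays the mean log2 signal was 7.85 for erythroid, 8.83 for perichondrium and fibroblast, 7.45 for osteoclast and macrophage and 6.71 for endothelial markers. The difference between the erythroid list and the perichondrium and fibroblast list held in 4 of 5 animals. Its exact sign-flip p was 0.125 (two-sided), where 5 animals allow no p below 0.0625. That 86.7% of the 30 markers rose describes the pattern and does not test its source. Of the 5 osteoblast markers among them, 3 are also on the mineralization list. RNA from blood, marrow and bone cells in the dissected tissue therefore stays open. So does a lower share of chondrocytes, and so does a difference between the zones themselves, which was not tested.

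Col10a1, Alpl and Phospho1, 3 genes of the hypertrophy and mineralization lists, were higher in epiphyseal than in resting arrays, while the hypertrophy list did not pass camera (adjusted p = 0.101) and the mineralization list did not without the epiphyseal arrays of animals 1 and 2 (adjusted p = 0.211). Other cells in the epiphyseal arrays of animals 1 and 2 are argued against only as the whole source of these 3 calls, since 100% stayed called without those arrays. The 3 genes were picked as called, and the lists moved more. Without those arrays the mean change, resting minus epiphyseal, was -0.269 for the hypertrophy and -0.333 for the mineralization list. Leaving out the hypertrophic array of animal 4 in their place gave -0.507 and -0.623. Those arrays may thus carry a part of the pattern. Hypertrophic chondrocytes in the epiphyseal tissue may contribute: of 88 genes that rose by a log2 fold change of at least 3 from the proliferative to the hypertrophic zone, members of the other cell type lists left out, 84.1% had a higher epiphyseal than resting mean, against 13.6% of 22 genes that fell as strongly (76.1% and 18.2% without the epiphyseal arrays of animals 1 and 2, and 70.5% of the 88 within each of animals 4 and 5). Blood and muscle genes outside those lists, such as Hba-a3 and Tcap, were among the 88, so RNA of other cells may carry a part. Tcap did not follow the muscle list, however. Its mean signal was 5230 in epiphyseal and 1483 in resting arrays, while the muscle list had a mean log2 signal of 9.42 ± 1.76 (SD, n = 4) and 10.7 ± 1.87 (n = 5). The epiphyseal excess over resting, as a share of the hypertrophic excess, differed widely between genes. It was 11.9% for Col10a1, 10.6% for Alpl and 27.2% for Phospho1, and had a median of 9.6% and quartiles of 2.9% and 22.2% over the 88 genes. For Mmp13 it was 154.6% and for Ankh 140.8%, but 0.1% for Panx3 and 1.3% for Ihh. A difference between the tissues themselves was not tested, and a batch shared by epiphyseal and transition arrays cannot be told apart from these, as its slope over the called probe sets was 0.157, between the bounds of 0.1 and 0.3.

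Cell cycle genes were higher in hypertrophic than in transition arrays, with a list mean of 0.756 ± 0.221 (SE). The list's lead over the median signal of each array's tested probe sets cannot test the authors' scaling. A factor per array moves nearly all probe sets of that array alike. That lead changed by 0.635 ± 0.22 and, with quantile normalization, by 0.62 ± 0.223. The list passed camera, which compares it with other genes in the same way, under median scaling and quantile normalization (adjusted p = 5.61e-06 and 9.15e-05). With the scaling as deposited and an estimated correlation it did not pass camera (adjusted p = 0.447). For the list mean itself scaling stays open, since it was 0.502 ± 0.242 under median scaling. Cycling blood and marrow cells stay open: with the marker scores as covariates the mean was -0.301 ± 0.418, but these scores follow the zone, and with that standard error an unchanged mean would not have passed either. The transition arrays' label wording leaves a batch open as well, and no biological explanation was tested.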

How the results depend on the processing

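The settings that left out 1 array or a pair of arrays by name, and the marker scores, were chosen only after the data were seen. Of 285 called results of named genes, 247 had a value in every setting other than the marker scores, and 202 of these kept their direction and call in all. Of the other 38, 23 kept both where they had a value, and none of the 285 changed sign in those settings where one was given, while with the marker scores 12 of 259 did. With no replicate block 273 of 285 kept their call and 12 lost it (Gli1 between proliferative and resting at an adjusted p of 0.0734), and with a random replicate block 282 kept it; the block moved no count of calls by over 1.5 times. Of 38 called lists 25 kept their call in every setting other than the marker scores and the estimated correlation, under which 0 passed. Low signal limits dim probe sets: fewer probe sets are tested with the filter at the 75th percentile.

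The filter at the 75th percentile gave 449 lower from resting to proliferative, 587 lower from proliferative to transition, 652 higher from transition to hypertrophic, and 1000 higher and 1129 lower from proliferative to hypertrophic. Median scaling gave 1163 lower from transition to hypertrophic. Leaving out each animal gave 68 to 120 higher and 69 to 172 lower between resting and epiphyseal cartilage, and leaving out the hypertrophic array of animal 4 gave 139 and 185. Without the epiphyseal arrays of animals 1 and 2, 105 were lower, and the means of the endothelium and osteoclast lists were 0.639 and 0.297 (adjusted p = 0.461 for each). The marker scores as covariates gave 11 higher and 5 lower from transition to hypertrophic, 617 and 665 from proliferative to hypertrophic, and 11 passing lists; the median standard error was 0.601 in place of 0.242, and members of the scores were given no value. In all other cases the cause was not tested.

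Uncalled members of the hedgehog list changed sign near 0. From resting to proliferative, Dhh was -0.005 and Stk36 -0.012 with a pseudocount of 1, Disp1 0.062 with quantile normalization and 0.088 with median scaling, and Dhh -0.086 with array weights. Between epiphyseal and resting, Disp1 was -0.052 with no replicate block, -0.016 with a random replicate block and -0.250 without the epiphyseal arrays of animals 1 and 2, Stk36 -0.033 with only the zones compared, and Ihh 0.062 and Stk36 -0.022 with array weights. From transition to hypertrophic, Stk36 was 0.010 with a pseudocount of 64 and 0.056 with array weights, and Sufu 0.085 with array weights. From proliferative to hypertrophic, Sufu was -0.042 with quantile normalization and -0.066 with median scaling.

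With the marker scores, values of changed sign from transition to hypertrophic were Dhh -0.053, Smo 0.145, Gli2 -0.764, Hhip -0.757, Sufu 1.933, Boc -1.238, Prc1 -0.039, Kdr -1.626, Tek -0.414, Tnc -0.536, Dusp6 -0.040, Igfbp5 -0.397, Coro1a -0.582, Crabp2 -0.832, the cell cycle list -0.301 and the hypoxia list 0.115. From proliferative to hypertrophic they were Stk36 -0.145, Esam -0.197, Kdr -2.078, Coro1a -1.465 and the hypoxia list 0.121, between epiphyseal and resting Disp1 -0.277 and the endothelium list 0.488, and from resting to proliferative Dhh -0.110 and Sufu -0.184.

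Leaving out each animal, the transition array of animal 5 or the hypertrophic array of animal 4, the ranges of uncalled members that crossed 0 were as follows. The last array gave the highest values of Dhh between epiphyseal and resting and of Sufu in the hypertrophic zone, and the transition array the lowest of Gli2. Dhh had no value without animals 1, 3 or 5 and Stk36 none without animal 4, as they then missed the filter, so their ranges rest on the other settings. Between epiphyseal and resting they were Ihh -0.934 to 0.275, Disp1 -0.147 to 0.263, Dhh -0.270 to 0.217, Stk36 -0.033 to 0.078 and Sufu -1.177 to 0.004. From resting to proliferative they were Stk36 -0.062 to 0.323, Disp1 -0.032 to 0.023 and Dhh -0.011 to 0.329, and from proliferative to transition Dhh -0.137 to 0.146 and Sufu -0.048 to 0.344. From transition to hypertrophic they were Stk36 -0.221 to 0.217, Sufu -0.318 to 0.235 and Gli2 -0.158 to 0.465, and from proliferative to hypertrophic Sufu -0.158 to 0.416.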

Other observations

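The 17 gene families in this part were defined by their symbols and the tests on them were chosen only after the named genes had been seen, with Fisher's exact test (two-sided) adjusted over 170 tests. That test takes genes as independent units, while genes of a family can move together on the same arrays. Its p-values may therefore be too small, and they do not measure the spread between animals. Kinesin genes, motor proteins of which several act in cell division, fell from the proliferative to the transition zone in 11 of 25 members (44% against 5% of other genes, adjusted p = 2.06e-06), Kif23 and Kif15 among them. Homeobox genes of the Hox clusters fell from the proliferative to the hypertrophic zone in 6 of 12 members (50% against 8.9%, adjusted p = 0.00623), including Hoxa9, Hoxa10 and Hoxa5 (Hoxa10 under 2-fold without replicate 3, at -0.95, adjusted p = 0.000162). A further 1 of the 12 rose (8.3% against 10.3% of other genes). Collagen genes rose over the same step in 13 of 33 members (39.4% against 10.2%, adjusted p = 0.000926) and fell in 5 (15.2% against 8.9%, adjusted p = 0.68). Those that rose included Col6a1, Col6a2 and Col10a1, and also Col1a1 and Col1a2 of the osteoblast list and of the perichondrium and fibroblast list. S100 genes, which encode calcium-binding proteins, rose in 7 of 12 members (58.3% against 10.2%, adjusted p = 0.00203), S100a8 and S100a9 of the leukocyte list among them. From the resting to the proliferative zone, matrix metalloproteinase genes fell in 5 of 11 members (45.5% against 3.9%, adjusted p = 0.00156), with Mmp16, Mmp9 and Mmp15, but in 2 members with median scaling or quantile normalization and in 1 to 4 when leaving out each animal. Without replicate 1 Mmp9 was not called (adjusted p = 0.115) and Mmp15 had no value. Mmp9 belongs to the osteoclast and macrophage list, of which 1 of 13 members fell in the same comparison (2 adjusted over the list alone), at a list mean of -0.915 (camera adjusted p = 0.0358; adjusted p = 0.658 with an estimated correlation). That list did not pass without replicate 1 (adjusted p = 0.133) or 3, with quantile normalization (adjusted p = 0.0549), with a pseudocount of 64 or with no trend. Under those scalings the counts were 11 and 11 for kinesins, 6 and 6 for Hox genes, 12 and 12 for collagens and 6 and 7 for S100 genes, and when leaving out each animal they were 11 in each case for kinesins, 4 to 7 for Hox genes, 12 to 13 for collagens and 6 to 7 for S100 genes. Not every family test that passed is described here. From the resting to the proliferative zone S100 genes fell in 4 of 12 members (33.3% against 3.9%, adjusted p = 0.0179), or 1 to 4 when leaving out each animal. In that step 2 of the 12 rose (adjusted p = 0.204). Collagens were lower in resting than in epiphyseal cartilage in 5 of 33 members (15.2% against 1%, adjusted p = 0.00125), or 3 to 4 when leaving out each animal.

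Other groupings of the same arrays were fitted to see how many calls a chance division gives, with 100 of 126 divisions run per comparison. The real division gave the most calls in each (1 of 100): 290 against at most 26 for resting and epiphyseal, 1170 against 169 for proliferative and resting, 1619 against 391 for transition and proliferative, 1781 against 879 for hypertrophic and transition, and 3585 against 1465 for hypertrophic and proliferative. Most of the divisions run put both zones of some animals on one side, however, unlike the real one, so that share cannot exclude chance. Of the 16 divisions that part every pair, 12 to 14 were run, and the others gave at most 1, 0, 8, 51 and 140 calls, but 16 are too few for a share below 0.05 (the smallest is 0.0625).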
